A study of Danio rerio with 6 samples.

How the data were processed

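The study sequenced polyadenylated RNA from pools of 50 whole zebrafish larvae at 7 days post fertilization. Per the labels, 3 pools were wild type and 3 were homozygous znf469 mutants, all kept at 28.5 °C, and each pool gave 1 library of paired 150 bp reads from fragments of about 200 bp. The deposited table holds 45602 RefSeq transcripts of 23876 genes with 1 signal value per library, and it names no unit. In each library every signal value was a whole multiple of the smallest positive value to within 0.001 (100% of values in each of the 6 libraries), so the deposited signal was taken as read counts that the authors divided by 1 factor per library. The value of 1 read ranged from 0.937 in mutant replicate 1 to 1.08 in mutant replicate 2. In wild type replicate 3 it was 0.990, so close to 1 that the step is harder to tell from rounding than in the other 5. The build was GRCz11, per the submitters' processing notes. The aligner, the counter, their settings, the strand setting and the treatment of reads shared by isoforms or gene copies are not given in the sources used here. Per the file headers, the deposited table also gives a log2 fold change, a p-value and a q-value per transcript. The sign of that log2 fold change was mutant over wild type in 99.8% of transcripts. The authors' test is not given in the sources used here.

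Isoforms of 1 gene shared reads in the deposited table: of the transcripts of the 9409 genes with more than 1 transcript, 6.91% had the same reads in all 6 libraries as another transcript of their gene. Each gene was therefore represented by the transcript with the highest mean over all 6 libraries. This choice was made after the table was opened, and sums over transcripts and every transcript by itself were run as alternatives. A gene's value is thus that of 1 annotated transcript, and near-identical gene copies, such as actins, globins and class I histocompatibility genes, may have exchanged reads in a way the table cannot show. Depth is given as recovered reads over all transcripts, where a read shared by isoforms is counted more than once.

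The design written before the data were examined assumed raw counts and named the quasi-likelihood test of edgeR, with a fallback for a table without counts. Because the table held normalized values, the fallback was the main test: limma on log2(value + 1), for genes with a value of 1 or more in at least 3 libraries, with an intensity trend and without robust weights. The p-values were adjusted by the Benjamini-Hochberg method over 22803 genes, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Errors of values are SD over 3 libraries, and SE is given for log2 fold changes. The lists of genes, the rule for the genes named and the first set of other settings were also fixed before the data were examined. Of 1206 members in 33 lists, 1114 were found in the table by symbol or by an older symbol in a reference table of the assembly GRCz12tu. The 13 members of the list of mitochondrial transcripts matched no row, and that list was not tested. Lists were tested with camera of limma on the same log2 values at a preset correlation of 0.01 between genes, adjusted over 32 lists. The design had named the weighted log2 CPM of voom for this step, which needs counts. At the preset correlation, splits of the libraries that cut across the groups also called 6 to 24 lists. Such splits hold the groups in unequal shares, so part of a group difference stays in them. Their counts are therefore no rate of false calls. The correlation estimated per list was 0.0142 to 0.677, above the preset value, so a call at the preset value alone is weak evidence. The same lists were tested with a correlation estimated per list, and with fry, whose directional test asks if genes of a list move one way on balance and whose mixed test asks if they change in either direction. Counts of members past the threshold are given over all genes and adjusted over the list alone.

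The text names znf469, and then genes past the threshold whose libraries did not overlap between groups, with a symbol other than a clone or locus name and a mean CPM of 1 or more. These were the 5 with the largest fold change and the next 3 with the smallest p in each direction. From each called list it names the 2 members with the smallest p in the direction of the list, and it names 10 genes of the fibrillar matrix whatever their p. Some items that these rules take are not reported here. Other genes named as examples were chosen after their values were seen. Genes near znf469 were compared with the rest by Fisher's exact test (two-sided), with positions from the GRCz12tu table used only for which genes lie near each other, and 94.4% of tested genes had a place. No coordinates are given, since that assembly is not the build of the table.

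Settings chosen in that way were DESeq2, limma-voom, and edgeR with RLE scaling or total counts on the recovered reads, no filter, a stricter filter, the replicate number as a block, each library left out in turn, library sizes without the 1% most abundant genes, an adjusted p threshold of 0.01, a fold minimum of 2, other list tests and windows of 2 and 10 Mb. The block was run in limma in place of edgeR, and the planned camera test with the block is part of it. Added after the data were seen were edgeR with TMM on the recovered reads, TMM scaling before limma, pseudocounts of 0.5 and 10, summed transcripts, every transcript as a feature, a covariate from the circadian clock list, and the fit without the 2 libraries that stood apart. The pools kept in that last fit also differ between groups in clock genes such as per3, so its counts cannot be assigned to genotype alone. The 2 libraries were left out because they lay far from the others of their groups, which lowers the spread within groups by selection. The p-values and counts of that fit are therefore biased towards more calls wherever they are given below. On the recovered reads, edgeR with TMM called 1037 genes and DESeq2 called 1468.

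The limma step was tested on data simulated for the comparison of znf469 mutant against wild type, over 22769 genes, with 50 genes changed at each fold size. It called 8% of genes changed 1.5-fold, 66% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 5 of the 142 genes it called had not been changed. No called gene had the wrong sign (0). The changed genes were drawn from those with at least 50 expected reads per library. The spread between libraries was set in advance, independently for each gene, and was not estimated from these data. The shares called need not hold for the real libraries. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. Bootstrap intervals used 2000 resamples, are for the median over the genes of a list and do not measure the spread between pools. Exact binomial intervals are at the 95% level and cover counting error only.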

Results

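Gene expression was measured by RNA sequencing in whole zebrafish larvae at 7 days post fertilization. The comparison was between wild type larvae and larvae homozygous for a mutation in znf469, the zebrafish counterpart of the zinc finger gene ZNF469 that is mutated in human brittle cornea syndrome. Each group had 3 libraries, each from a pool of 50 larvae. Reads over all transcripts came to 18988339, 18602183 and 19156581 in wild type replicates 1 to 3 and to 19101870, 18161628 and 17023269 in mutant replicates 1 to 3. Reads over 1 transcript per gene ranged from 8111192 to 9683579, and the 10 most abundant genes took 8.31% to 11.7% of them. The most abundant gene was actc1b, a striated muscle actin, in 5 libraries and myhz1.1, a fast muscle myosin, in mutant replicate 3. Replicates of a group differed by more than sampling noise (chi-square per gene from 5.76 to 23.5 over the 6 pairs), so each was counted as 1 sample. The labels do not say that the pools came from separate clutches, and the p-values measure only the spread between these pools. On the first 2 principal components of 19277 genes (47.2% and 27.2% of the variance), wild type replicate 1 and mutant replicate 2 stood apart from the other libraries of their groups, with scores of 60.4 and -53.0 on the second component.

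The comparison addresses the part that znf469 plays in the making of the extracellular matrix, the subject of the series title. The transcript of znf469 itself did not differ between groups, with a normalized read count of 233 ± 54.2 (SD, n = 3) in wild type and 210 ± 23.4 (SD, n = 3) in mutant pools. The difference on the log2 scale was -0.13 (SE 0.20, limma with Benjamini-Hochberg adjusted p = 0.786). The libraries held 313, 202 and 208 reads of it in wild type and 249, 173 and 203 in the mutant. A mutation need not lower its own mRNA, so this level does not check the labels. In the authors' deposited table the log2 fold change of znf469 was -0.15 with a q-value of 0.797.

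Fibrillar collagen transcripts were far lower in the mutant. The transcript of col1a1a, an alpha chain of type I collagen, fell from 18148 ± 1254 to 2461 ± 1702 normalized read counts (SD, n = 3), a log2 fold change of -3.09 (SE 0.37, limma with Benjamini-Hochberg adjusted p = 0.00181). The other type I chains col1a1b and col1a2 fell by 2.96 each on the log2 scale, to 1616 ± 624 and 1135 ± 494. Among the type II collagen genes, the main collagens of cartilage, col2a1a fell from 10317 ± 1834 to 1145 ± 436 and col2a1b from 3819 ± 402 to 640 ± 152. Of the 16 fibrillar collagens tested, 11 fell, none rose (0) and 5 did not pass, and 14 fell when adjusted over the list alone. The smallest p-value belonged to the minor fibrillar chain col5a3b, at -3.42 (SE 0.23, limma with Benjamini-Hochberg adjusted p = 0.000187). The type V chains col5a1 and col5a2a, which take part in fibril assembly, fell by 1.45 and 0.77. The list had a median log2 fold change of -2.41 and was called by the directional test of fry (Benjamini-Hochberg adjusted p = 0.00976). It was also called by camera at the preset correlation (adjusted p = 1.92e-21). The stricter form of camera did not call it (unadjusted p = 0.00961, adjusted p = 0.224 with an estimated correlation). With each library left out in turn the list was called (adjusted p of at most 2.92e-16) with 10 or 11 members lower, and so were col1a1a, col1a1b, col1a2, col2a1a, col2a1b, col5a1 and col5a3b. The call of col5a2a ended without wild type replicate 2 or 3 or mutant replicate 1 or 3, with adjusted p from 0.0675 to 0.205.

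**Figure D1:**
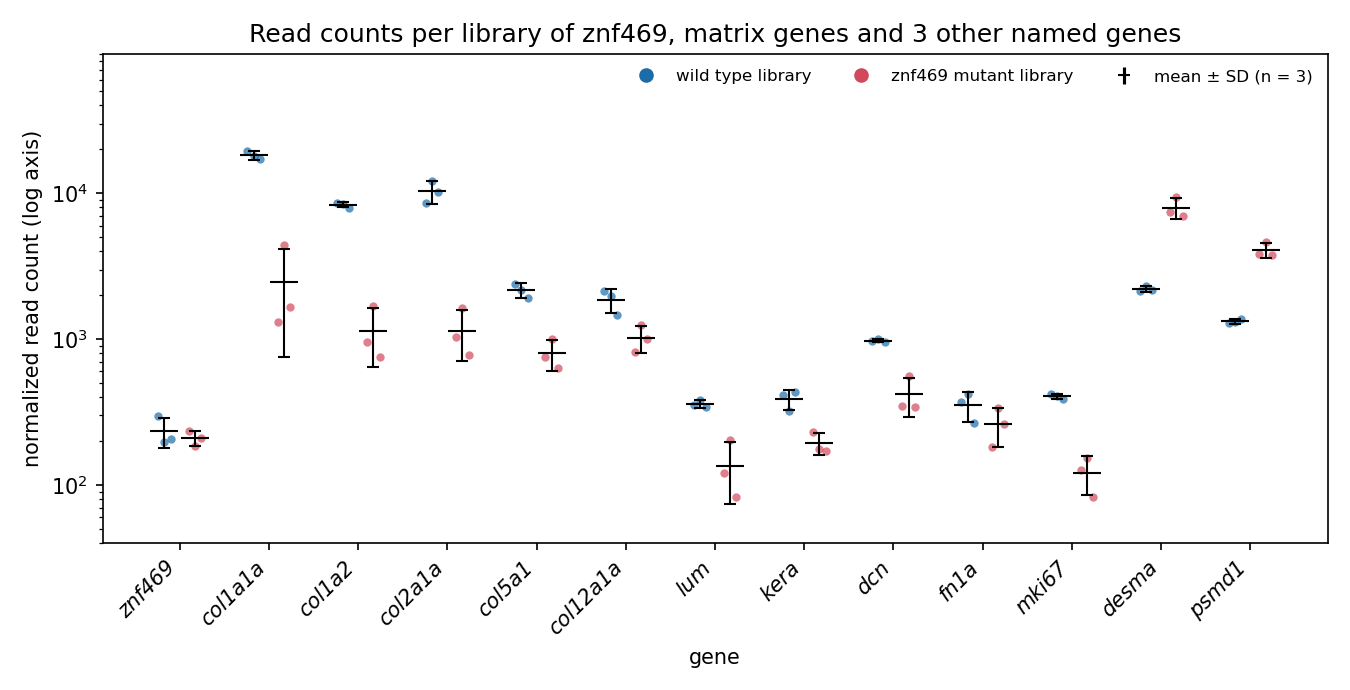
Normalized read counts (log axis) of znf469, 9 genes of the fibrillar matrix, mki67, desma and psmd1 in each of the 3 wild type (blue) and 3 mutant (red) libraries, with the mean and SD per group in black. For col1a1a the mutant mean was 2461 against 18148 in wild type, while znf469 (210 against 233) and fn1a (261 against 352) overlapped between groups.

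Other collagens and proteins bound to collagen fibrils were also lower. In the list of other collagens, 10 of 26 fell, 1 rose and 15 did not pass (18 lower and 2 higher adjusted over the list alone), with a median of -0.95. Type IX collagen, which coats cartilage fibrils, had the largest falls, with col9a3 at -3.83 (SE 0.32, limma with Benjamini-Hochberg adjusted p = 0.000341), from 1587 ± 160 to 121 ± 61.9, and col9a2 at -3.08 (SE 0.25, adjusted p = 0.000295). The fibril-associated collagen col12a1a fell by 0.87, while col8a1a, a network-forming collagen and the 1 member that rose, was at 0.92. Of 17 small leucine-rich proteoglycans, which bind collagen fibrils and set their spacing, 6 fell (8 adjusted over the list alone). They included lum (lumican, -1.50), kera (keratocan, -1.01) and dcn (decorin, -1.26), all abundant in the corneal stroma, and the largest falls were in epyc (epiphycan of cartilage, -2.76) and ecm2 (-2.30). Both lists were called at the preset correlation (camera, Benjamini-Hochberg adjusted p = 7.15e-11 and 2.64e-08). Neither call held in the stricter test (adjusted p = 0.224 with an estimated correlation for both). By the directional test of fry both lists passed (Benjamini-Hochberg adjusted p = 0.024 and 0.026). In limma, the calls of lum, kera and dcn ended without wild type replicate 2 (adjusted p = 0.0969, 0.0517 and 0.0573), those of lum and kera also without wild type replicate 3 (0.0566 and 0.0733) or mutant replicate 3 (0.0554 and 0.0906), and that of lum without mutant replicate 1 (0.0664). The call of col12a1a ended without wild type replicate 1 or 2 or mutant replicate 1 or 3, with adjusted p from 0.0711 to 0.198. Without wild type replicate 2, 6 other collagens and 2 proteoglycans were lower, and 16 and 11 were without both libraries that stood apart.

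Several further matrix lists moved the same way by smaller amounts. In basement membrane genes, 9 of 28 fell (13 adjusted over the list alone), led by col7a1, the collagen of anchoring fibrils, at -2.84 (SE 0.26, limma with Benjamini-Hochberg adjusted p = 0.000491), and the laminin chain lamb4 at -1.90. Of 43 genes of elastic fibres and matrix glycoproteins, 9 fell (14 adjusted over the list alone), among them postnb (periostin, -1.74) and elnb (elastin, -2.04). In the list of genes of brittle cornea and Ehlers-Danlos syndromes, 7 of 20 fell (13 adjusted over the list alone), and 6 of these 7 were the collagens col1a1a, col1a1b, col1a2, col5a1, col5a2a and col12a1a given above. Among 44 genes that modify, fold or cross-link collagen, 3 fell and 1 rose (7 lower and 2 higher adjusted over the list alone). Here the cross-linking enzyme loxl3a was at -3.20 and the prolyl hydroxylase p3h1 at -1.42, while loxl5b, another lysyl oxidase relative, was at 1.83. These 4 lists were called at the preset correlation (camera, Benjamini-Hochberg adjusted p = 7.30e-10, 6.27e-06, 4.71e-11 and 0.0170, in the order given). Of the 4, the directional test of fry called only the brittle cornea list (Benjamini-Hochberg adjusted p = 0.068, 0.117, 0.024 and 0.344). In the stricter form of camera none was called (adjusted p = 0.349, 0.522, 0.224 and 0.681 with an estimated correlation). The collagen processing list lost its call without wild type replicate 1 (adjusted p = 0.108), elnb lost its limma call without wild type replicate 2 (adjusted p = 0.0649), and p3h1 when any library but mutant replicate 2 was left out (adjusted p from 0.0711 to 0.141). With 1 library left out, 2 to 10 basement membrane genes, 1 to 10 elastic fibre and glycoprotein genes and 1 to 8 collagen processing genes were lower, the fewest without wild type replicate 2 (in some cases with ties) and the most without mutant replicate 2. Without both libraries that stood apart these numbers were 13, 16 and 11, and 12 genes of the brittle cornea list were lower. The adhesion glycoprotein fn1a, at -0.45, did not pass (limma with Benjamini-Hochberg adjusted p = 0.394).

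Markers of cartilage fell. In the cartilage list 11 of 25 genes fell (15 adjusted over the list alone), and the smallest p-values were those of the collagens col11a2 (-3.19) and col2a1a (-3.22). Without the members held by another list, most of them collagens, the cartilage median was -0.49 and the call remained (camera, Benjamini-Hochberg adjusted p = 0.0295). Of 23 fibroblast and tendon genes only tnmd (tenomodulin, a tendon protein) passed in limma, at -1.85 (1 adjusted over the list alone), and pdgfrl was at -1.05 (Benjamini-Hochberg adjusted p = 0.0841). No bone gene passed in limma (0 of 21, with 4 lower adjusted over the list alone, 6 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with edgeR), panx3 was at -1.91 (adjusted p = 0.0692) and entpd5a, needed for bone mineralization, at -1.35 (adjusted p = 0.0728). The cartilage, fibroblast and bone lists were called at the preset correlation (camera, Benjamini-Hochberg adjusted p = 1.56e-09, 0.00539 and 0.00718). Among these, fry called only the cartilage list in its directional test (Benjamini-Hochberg adjusted p = 0.024, 0.344 and 0.367). With the correlation estimated, camera called none of them (adjusted p = 0.224, 0.577 and 0.610 with an estimated correlation). The bone list had a median of -0.75 to -0.17 with 1 library left out, and its call ended with edgeR under RLE or TMM scaling and with the clock covariate (adjusted p = 0.0513, 0.0517 and 0.0537). Without both libraries that stood apart, 7 fibroblast and tendon genes passed in limma, pdgfrl among them (adjusted p = 0.0151), with a list median of -0.61. In the same fit 12 bone genes passed, among them panx3 and entpd5a (adjusted p = 0.0306 and 0.0343). Leaving out libraries because they stood apart lowers the spread within groups, which by itself favours such calls. Fibroblast and tendon genes numbered 2 with DESeq2 or the clock covariate, and bone genes 2 with the replicate block and 1 without mutant replicate 2.

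Genes of the cell cycle formed the second group with a large shift. Of 42 tested, 22 fell, none rose (0) and 20 did not pass, 37 fell when adjusted over the list alone, and the median was -1.50. The kinetochore motor cenpe fell from 146 ± 16.7 to 34.1 ± 2.90 (SD, n = 3; -2.06, SE 0.23, limma with Benjamini-Hochberg adjusted p = 0.00117), and mki67, a marker of dividing cells, from 405 ± 16.2 to 121 ± 36.2 (-1.78, SE 0.23, adjusted p = 0.00270). The DNA topoisomerase top2a was at -2.13, cyclin A2 (ccna2) at -2.62 and the replication clamp pcna at -0.95. The list was called at the preset correlation (camera, Benjamini-Hochberg adjusted p = 3.15e-27), also with each library left out (adjusted p of at most 9.19e-23), but not in the stricter test (adjusted p = 0.224 with an estimated correlation). It passed in the directional test of fry (Benjamini-Hochberg adjusted p = 0.024). The number of members that fell was 6 without wild type replicate 2, 10 without wild type replicate 3 or mutant replicate 3, 12 without mutant replicate 1, 31 without mutant replicate 2 and 38 without both libraries that stood apart.

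Lists of skeletal muscle, epidermis, erythrocytes, pigment cells and neurons also had negative medians, from -0.61 for pigment cells to -0.13 for neurons. In muscle, 9 of 62 genes fell (17 adjusted over the list alone), led by casq1a, the calcium-binding protein of the sarcoplasmic reticulum, at -2.34 (SE 0.21, limma with Benjamini-Hochberg adjusted p = 0.000373), and the actin acta1b at -2.41. The reads of acta1b may be split with those of other actins. Among epidermal genes, 6 of 38 fell (11 adjusted over the list alone), with the keratins krtt1c19e at -1.85 and krt5 at -1.59. Of 22 erythrocyte genes, 4 fell (8 adjusted over the list alone), with the globins hbbe1.1 at -1.99 and hbae3 at -1.46, whose reads may be shared with other globin copies. Of 30 pigment cell genes, 4 fell (8 adjusted over the list alone), including the melanin synthesis genes tyrp1a at -1.56 and tyrp1b at -1.11. In neurons 1 of 44 genes fell, the neurofilament nefmb at -0.77 (0 adjusted over the list alone, with 7 at an unadjusted p under 0.05 in limma, 2 lower with DESeq2 and 1 with edgeR over all genes), and nefma was at -0.57 (adjusted p = 0.106). The 5 lists were called at the preset correlation (camera, Benjamini-Hochberg adjusted p = 3.34e-10, 7.79e-07, 0.000407, 5.59e-05 and 0.0416, in the order given). In its directional test fry called only the pigment cell list (Benjamini-Hochberg adjusted p = 0.0727, 0.344, 0.273, 0.024 and 0.344). No camera call was kept in the stricter test (adjusted p = 0.349, 0.577, 0.577, 0.224 and 0.696 with an estimated correlation). The neuron list lost its call without wild type replicate 3 (adjusted p = 0.284), mutant replicate 2 (0.411) or mutant replicate 3 (0.0758), with the replicate block (0.0523), RLE scaling (0.0602), total counts (0.0675), edgeR with TMM (0.0600) or the clock covariate (0.0534), and without both libraries that stood apart (0.135). Leaving out wild type replicate 2 ended the limma calls of krt5, hbbe1.1, hbae3, tyrp1a, tyrp1b and nefmb (adjusted p = 0.0692, 0.0548, 0.135, 0.0913, 0.144 and 0.222), and of these only the call of hbbe1.1 passed with every other library left out. With 1 library left out, 3 to 20 muscle genes, 1 to 15 epidermal genes, 0 to 7 erythrocyte genes and 0 to 6 pigment cell genes were lower, the most without mutant replicate 2. Neuron genes that were lower numbered 0 to 2 in these fits and 0 with the replicate block. Without both libraries that stood apart, the 5 lists had 37, 20, 8, 9 and 12 lower members, with nefma among them (adjusted p = 0.00241).

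Among the lists that were higher, the shifts were small. The 6 lists were cholesterol synthesis, lens, heat shock and oxidative stress, circadian clock, interferon and inflammation, and exocrine pancreas, with medians of 0.34, 0.28, 0.24, 0.21, 0.18 and 0.17 and adjusted p of 0.00357, 0.0314, 0.0315, 0.00596, 0.0295 and 0.0315 (camera, Benjamini-Hochberg). With the correlation estimated, all 6 calls were lost (adjusted p = 0.577, 0.834, 0.764, 0.577, 0.610 and 0.813 with an estimated correlation, in the same order). In the heat shock list 2 of 33 genes rose (3 adjusted over the list alone): the small heat shock gene hspb9, at 1.62 (SE 0.27, limma with Benjamini-Hochberg adjusted p = 0.00944), and the chaperone hsp90aa1.1, at 1.03. The count was 0 without mutant replicate 3, 4 without both libraries that stood apart and 7 with the clock covariate. In the clock list 3 of 38 rose (3 adjusted over the list alone): the nuclear receptor rorcb (3.66), clockb (0.71) and nfil3-6 (1.03). The count was 1 with limma-voom, total counts, library sizes without the most abundant genes or summed transcripts, 0 to 4 with 1 library left out, and 15 without both libraries that stood apart. Other clock genes differed within the groups, as per3 did (564, 88.3 and 86.1 in wild type, 354, 95.9 and 518 in the mutant). In the cholesterol list 1 of 29 rose, the LDL receptor gene ldlra at 0.80 (2 adjusted over the list alone), and the sterol carrier stard4 was at 120 ± 18.3 against 60.5 ± 16.1 (adjusted p = 0.0633). The count was 0 without wild type replicate 2 or 3 or mutant replicate 3, and 7 with the clock covariate. The gene stard4 passed with DESeq2, limma-voom, total counts, summed transcripts, the clock covariate and without both libraries that stood apart (adjusted p from 0.00649 to 0.0477). In the pancreas list 1 of 28 rose, the phospholipase pla2g1b, from 245 ± 68.7 to 523 ± 134 (4 higher and 1 lower adjusted over the list alone), and rnasel3 was at 1.56 (adjusted p = 0.0528). The count was 0 to 2 with 1 library left out, 6 with DESeq2 and 7 without both libraries that stood apart, and rnasel3 passed in both of the last 2 (0.0253 and 0.00629). No gene of the lens list passed in limma (0 of 59, and 0 adjusted over the list alone, with 12 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with edgeR); crygm7 was at 1.15 and grifin at 0.61. With the clock covariate 8 lens genes passed, these 2 among them (adjusted p = 0.0201 and 0.0151). No gene of the interferon list passed in limma (0 of 38, and 0 adjusted over the list alone, with 11 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with edgeR); mxb was at 2.73, read mainly in mutant replicate 1 (30, 5 and 2 reads in the 3 mutant libraries), and il11a at 1.76. The count was 4 without wild type replicate 1, where il11a passed (adjusted p = 0.0427), 6 without both libraries that stood apart, and 1 with the replicate block, where mxb passed (0.0346), with the clock covariate or without mutant replicate 3. Leaving out mutant replicate 2 ended the calls of the lens, heat shock, pancreas and interferon lists (adjusted p = 0.408, 0.678, 0.678 and 0.0603), leaving out wild type replicate 1 those of the lens and heat shock lists (0.360 and 0.150), wild type replicate 3 those of the pancreas and interferon lists (0.489 and 0.110), wild type replicate 2 or mutant replicate 1 that of the interferon list (0.132 and 0.0825), and mutant replicate 3 that of the clock list (0.235). The clock list also lost its call with the clock covariate, which is built from the same list (median 0.11, adjusted p = 0.678). The interferon list lost its call with RLE scaling, total counts, edgeR with TMM, the stricter filter and the clock covariate as well (adjusted p = 0.118, 0.144, 0.124, 0.0762 and 0.260), the lens list with the stricter filter (0.0587) and the pancreas list with the clock covariate (0.0980). Without mutant replicate 2 the medians of the lens and pancreas lists were negative, at -0.12 and -0.03. With 1 library left out, the median was 0.08 to 0.38 for the clock list and 0.14 to 0.38 for the heat shock list. For the interferon list it was 0.11 to 0.35, and for the cholesterol list 0.26 to 0.40. Without both libraries that stood apart, the lens list was lower, at -0.25 (adjusted p = 0.0355), and the cholesterol, pancreas and heat shock lists were not called (adjusted p = 0.188, 0.131 and 0.980). The heat shock list also lost its call with total counts (0.0540). All 6 genes named as rising in these lists by the rule lost their limma calls with 1 library or more left out, including mutant replicate 3 in each case (adjusted p from 0.0523 for hspb9 to 0.140 for pla2g1b).

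**Figure D2:**
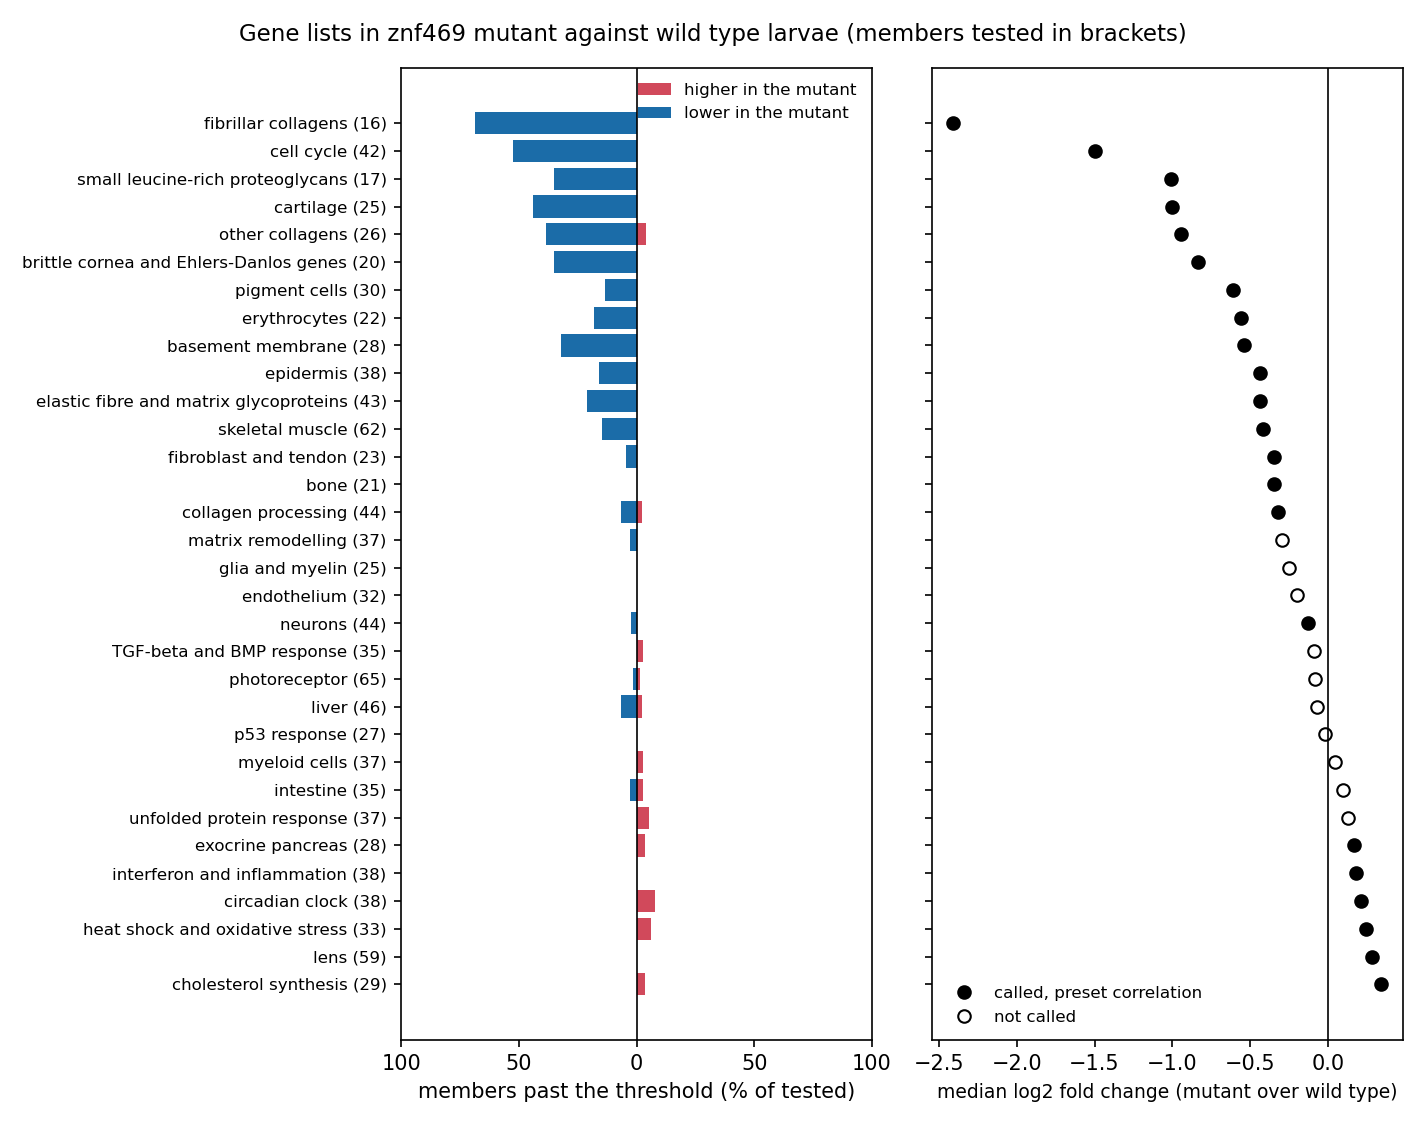
Percent of tested members past the adjusted p threshold of 0.05 in each of 32 lists, higher (red) or lower (blue) in the mutant (left), and the median log2 fold change of each list (right), where filled points are lists called by camera at the preset correlation and open points are not. Fibrillar collagens lie lowest, with a median of -2.41 and 11 of 16 members lower, followed by the cell cycle, with -1.50 and 22 of 42.

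The remaining 10 lists were not called. They were matrix remodelling (camera, Benjamini-Hochberg adjusted p = 0.128), TGF-beta and BMP response (0.797), photoreceptor (0.416), liver (0.811), intestine (0.376), glia and myelin (0.301), myeloid cells (0.301), endothelium (0.376), unfolded protein response (0.0779) and p53 response (0.670). Of these, the unfolded protein response list was called with DESeq2, without mutant replicate 1 or 3 and with the clock covariate (adjusted p = 0.0472, 0.0121, 0.0243 and 0.0196), and matrix remodelling without wild type replicate 3 and with the clock covariate (0.0198 and 0.0349). The glia list was called without wild type replicate 1 and without both libraries that stood apart (0.0372 and 0.00497), and the intestine and myeloid lists without mutant replicate 1 (0.0303 and 0.0255). For TGF-beta and BMP response the median (-0.09) and the test pointed down while the mean was 0.05, and for the p53 response the median was -0.02 while the mean (0.02) and the test pointed up. Single members of these lists passed in limma with Benjamini-Hochberg adjustment: the liver transport genes tfa (transferrin, -1.40) and serpina7 (-2.74) fell, and the chaperone gene dnajb9b (1.38) rose.

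Across all 22803 genes tested, 526 rose and 497 fell in the mutant, 1023 in all (limma, Benjamini-Hochberg adjusted p under 0.05), and 4149 had an unadjusted p under 0.05. A change of at least 2-fold was found in 761 of the 1023, 349 higher and 412 lower. All 1023 had libraries that did not overlap between groups, which held for 23.4% of all tested genes, where chance gives 10%. By the rule for the genes named, which asks for a mean CPM of 1 or more, the largest rises were in ttc29 (a gene of motile cilia, 4.33), casp6l2 (a caspase, 4.05), the serpin serpinb14 (3.85), rorcb (3.66) and the glucuronosyltransferase ugt5a2 (3.54). Among these, serpinb14 rose 14.8-fold to 310 ± 28.0 (SD, n = 3), while ttc29 and casp6l2 had 0 or 1 read in each wild type library. The order depends on the pseudocount: with 10, serpinb14 was at 3.38, ttc29 at 1.94 and casp6l2 at 1.53. Other rises with small p-values were in txnl1 (1.91), a thioredoxin-like protein bound to the proteasome, desma (1.84), the desmin of muscle intermediate filaments, and psmd1 (1.62), a subunit of the proteasome. By the same rule the largest falls were in sc:d217 (-5.40), mhc1uma, ftr51 (a gene of the finTRIM family, -4.04), col9a3 (-3.83) and slx4ip (-3.59). With 0, 0 and 1 reads of sc:d217 in the mutant libraries, the size of its fall is uncertain. It was -2.60 with a pseudocount of 10 and -7.21 with DESeq2. The class I histocompatibility gene mhc1uma had 31, 38 and 29 reads in wild type and 0 in each mutant library, so it was at least 31.3-fold lower (floor of 3 counts over the group). The smallest p-value of all was that of irs2a, an adaptor of the insulin receptor, which fell from 1057 ± 40.8 to 126 ± 17.3 (-3.07, SE 0.16, limma with Benjamini-Hochberg adjusted p = 7.34e-05). Of the 53 called genes named by the rule, 34 were called with each library left out in turn. The number of genes called depended on the libraries. It was 244 without wild type replicate 2, 341 without mutant replicate 3, 431 without wild type replicate 3, 482 without mutant replicate 1, 1215 without mutant replicate 2 and 1345 without wild type replicate 1, and 5015 without both wild type replicate 1 and mutant replicate 2, which had stood apart. In the libraries kept by that last fit, per3 was at 88.3 and 86.1 in wild type and 354 and 518 in the mutant. The fit therefore mixes genotype with a difference in clock genes. Leaving out libraries because they stood apart also lowers the spread within groups, which by itself favours more calls. The share of called genes that were higher was 51.4%, with a range from 36.5% without mutant replicate 2 to 60.5% without wild type replicate 1. The authors' deposited table gave a q-value under 0.05 to 3797 transcripts of 2213 genes, 1876 of them higher and 1921 lower.

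Genes close to znf469 were compared with the rest of the genome, since a homozygous mutant line carries the founder chromosome around the target. On the chromosome of znf469, 33 of 669 tested genes had changed (4.93%), against 909 of 20856 elsewhere (4.36%), an odds ratio of 1.14 (95% interval 0.772 to 1.63, Fisher's exact test, two-sided, p = 0.443). Within 5 Mb, 12 of 150 genes had changed (8%), against 4.35% of the rest, an odds ratio of 1.91 (95% interval 0.961 to 3.46, Fisher's exact test, two-sided, p = 0.0416). Adjusted for the 2 tests by the Benjamini-Hochberg method this p was 0.0832, which did not pass. The odds ratio of the window was 1.16 without wild type replicate 1, and the raw p passed in neither that fit nor those without wild type replicate 2, mutant replicate 1 or mutant replicate 3 (0.598, 0.0664, 0.233 and 0.0592). The raw p passed in the other 2 such fits and with a window of 2 Mb, where the odds ratio was 2.75.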

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

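The tests with TMM, other pseudocounts, summed or single transcripts, the clock covariate and the fit without both libraries that stood apart were chosen after the results were seen. With 1 library left out, the genes changed numbered 244 to 1345 against 1023, the higher genes 142 to 814, the lower genes 102 to 771, those at least 2-fold changed 242 to 1032, and the odds ratio within 5 Mb of znf469 was 1.16 to 2.71. The clock covariate gave 1913 genes (1142 higher, 771 lower), every transcript as a feature 1673 (791 and 882, with 1216 at least 2-fold changed), and the fit without both libraries that stood apart 5015 (2551 and 2464, with 2482 at least 2-fold changed). An adjusted p threshold of 0.01 left 300 genes (162 and 138), and of the genes changed at least 2-fold 349 were higher, both by construction. Of 22 called lists an estimated correlation left 0 and fry 7, with 16 by its test in either direction. Fry kept the fibrillar collagen, other collagen, proteoglycan, brittle cornea, cartilage, pigment cell and cell cycle lists (directional test, adjusted p from 0.00976 to 0.0259). For these 7 lists the unadjusted camera p with an estimated correlation was 0.00961 to 0.0491, and all shared an adjusted p of 0.224. The lens median was -0.12 to 0.52 with 1 library left out (the lowest without mutant replicate 2) and -0.25 (camera, adjusted p = 0.0355, in a range of 4.73e-07 to 0.834 over all alternatives) without both libraries that stood apart. In that fit the median of the heat shock list stayed positive, at 0.12, while the test turned (adjusted p = 0.980, the highest in a range from 0.00164). The window around znf469, with a raw p of 0.0416, no longer passed with DESeq2 (odds ratio 1.63), limma-voom (1.78), RLE scaling (1.61), total counts (1.83), edgeR with TMM (1.65), the stricter filter (1.80), library sizes without the most abundant genes (1.73), pseudocounts of 0.5 (1.81) and 10 (1.79), summed transcripts (1.38), the clock covariate (1.60) or a window of 10 Mb (1.43). It still passed in 2 of the fits with 1 library left out and in 5 other settings. Among the latter was a window of 2 Mb, with the highest odds ratio (2.75). The cause of these shifts was not tested. In the fit without both libraries that stood apart the groups also differ in clock genes, and that choice of libraries favours calls. The log2 fold change of znf469 lay between -0.30 and 0.13 and passed under none of the alternatives, while the median of the fibrillar collagens lay between -2.95 and -1.61, and their call ended only with an estimated correlation (adjusted p = 0.224, the highest of all). Among the genes named by the rule, no called gene changed direction, and calls ended in 62 tests with 1 library left out and in 8 others. The values did not show that replicate numbers pair the pools. Deviations of same-numbered libraries correlated at 0.184, 0.183 and -0.394, and mutant replicate 3 correlated best with wild type replicate 1 (0.416). With so few libraries these correlations cannot exclude a pairing, and the labels state none. With the replicate block 980 genes were called, 875 of them shared with the 1023, and 20 lists, without the neuron and heat shock lists (adjusted p = 0.0523 for both). Depth limits genes of a few reads per library. Changes of 1.5-fold were called in 8% of simulated cases, a share that need not hold at the spread of these libraries.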

Other observations

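The lists of proteasome subunits, ribosome biogenesis factors and class I histocompatibility genes, and the tests of the clock covariate, connective-tissue cells, parental background, haplotypes and the other split of the libraries, were chosen after the results were seen. Transcripts of the proteasome, the complex that degrades tagged proteins, rose together in the mutant. Of 42 subunit genes 34 rose and none fell (0), with a median of 1.19 on the log2 scale, and the same counts adjusted over the list alone were 34 and 0. The regulatory subunit psmd1 was at 1.62, the ATPase psmc1b at 1.78 and the catalytic psmb7 at 1.33, and the partners usp14 (1.73), adrm1 (1.51), pomp (1.23) and vcp (1.12) also rose (limma with Benjamini-Hochberg adjusted p = 0.000643, 0.00107, 0.0116 and 0.0117 for these 4). Ribosome biogenesis factors, which process ribosomal RNA, rose in 45 of 92 cases with none lower (0), at a median of 0.78 (80 higher and 1 lower adjusted over the list alone), among them rrp12 (1.37), noc2l (1.26) and npm1a (1.19). With an estimated correlation the camera p was 0.0623 for the proteasome and 0.0306 for ribosome biogenesis, or 0.0935 and 0.0917 after adjustment over the 3 added lists, so neither passed. Leaving out 1 library gave 19 to 32 proteasome genes and 11 to 45 biogenesis genes that rose. Because psmd1 was among the smallest p-values that led to these lists, they are not independent evidence of the direction.

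Several genes known to respond to fasting, insulin or glucocorticoids rose while irs2a fell, and were picked after their values were seen. The transcript of igfbp1a, a binding protein of insulin-like growth factors, rose from 1014 ± 172 to 2062 ± 226 (SD, n = 3; limma with Benjamini-Hochberg adjusted p = 0.00932). The gluconeogenic enzyme pck1 rose from 7076 ± 836 to 14815 ± 3255 (adjusted p = 0.0218), and ddit4, an inhibitor of mTOR signalling, from 661 ± 65.9 to 1396 ± 114 (adjusted p = 0.00379). The glucocorticoid target fkbp5 was at 5606 ± 1790 against 1640 ± 1115 (adjusted p = 0.0269). A gene of another kind picked in the same way, the mineralization inhibitor mgp, rose from 2.62 ± 2.08 to 30.8 ± 12.6 (adjusted p = 0.00855). These genes formed no list, and their grouping was not tested.

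The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1023 changed genes (1 of 10 splits gave as many) and the highest other gave 359. For lists the real split gave 22 called and the other splits 6 to 24, and 2 of 10 splits gave as many. The split with 24 called lists had 0 changed genes. The other splits hold the groups in unequal shares, so part of a group difference stays in them and their counts are no rate of false calls. Estimated correlations lay between 0.0142 (pigment cells) and 0.677 (exocrine pancreas), above the preset 0.01. A list call at the preset correlation is therefore weak evidence by itself, which is why it is given with that at an estimated one.

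The fall of fibrillar collagens was weighed against 3 other explanations. Fewer connective-tissue cells with unchanged expression per cell would lower genes specific to those cells by as much. The 20 fibroblast and tendon genes with a mean value of at least 20 had a median of -0.34 (95% bootstrap interval -0.45 to -0.22). For the collagens it was -2.41 (-3.04 to -1.31). The median of all 23 fibroblast and tendon genes was -0.56 to -0.26 with 1 library left out and -0.61 without both libraries that stood apart. As a set they fell less than the collagens, but whether they mark the cells that make collagen was not tested. Cartilage genes held by no other list were also lower, with a median of -0.49. The comparison therefore cannot exclude a loss of collagen-making cells. As far as 1 clock score records it, a difference in the hour of collection is argued against by the fit with that covariate. There the collagen median was -2.24 (-2.87 to -1.67) and 13 of 16 were lower. The score cannot hold every phase: per2 was at 472 and 1163 in mutant replicates 1 and 3, which scored 0.564 and 1.11. Its genes include rorcb and clockb, which rose in the mutant, so hours that the score misses stay open. A difference in genetic background between the parents cannot be told apart from the mutation, since the labels do not say whether the wild type pools are siblings of the mutants and 62 genes were read in 1 group alone. An effect of the znf469 mutation therefore stays a hypothesis beside it, and so does a loss of collagen-making cells. Slower growth or poorer nutrition of the mutant larvae stay open as well and were not tested.

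Some genes had at least 3 reads in every library of one group and none in the other: 38 in wild type alone and 24 in the mutant alone. Counting noise is argued against by the other splits, which gave at most 5 such genes. Linkage to znf469 as the whole cause is argued against by 40 genes placed on other chromosomes: only 67.7% of the 62 had a place, but counting every unplaced gene on the znf469 chromosome gives 35.5% (95% exact interval 23.7 to 48.7). Class I histocompatibility genes, which differ between haplotypes, were among them (mhc1uma and mhc1ula in wild type, mhc1uba and mhc1uka in the mutant, 4 of the 15 that could pass; Fisher's exact test, two-sided, p = 7.83e-08), but the family was picked after members of it had been seen there, so this p-value decides nothing and different parental haplotypes remain an open possibility.

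The split of wild type replicate 1 and mutant replicates 1 and 3 from the other 3 libraries called 359 genes. Circadian clock genes were called more often than others (5 of 38, 13.2%, against 1.56%; Fisher's exact test, two-sided, p = 0.000308): per3, per1a, per1b, tefb and dbpb, with per3 at 564, 354 and 518 in the first set and at 88.3, 86.1 and 95.9 in the second. The split was picked after the results were seen and clock genes vary together, so this p-value decides nothing. Pools taken at different hours are a candidate explanation. Library size is argued against, since the sizes of both sets overlapped and their means had a ratio of 0.986. Beyond the clock genes, no biological explanation was tested for this split, because the design names no group that follows it.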
